A study of Drosophila melanogaster with 3 samples.

How the data were processed

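Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos collected 0 to 24 hours after laying, from a transgenic line that carries the CG14050 protein fused to enhanced green fluorescent protein (eGFP). Per the labels, an antibody against GFP was used for the precipitation, chromatin was sheared by sonication and fragments of 200 to 800 bp were kept. There were 3 biological replicates in 1 group. No control library was analysed here, although the labels name a control experiment and the deposited descriptions list a control file among the inputs of every peak list.

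The peak lists were made by the authors. For each replicate they deposited a list of ranked regions and a shorter thresholded list, each derived from the alignments of that replicate alone. They also deposited 4 pairs of such lists derived from the alignments of all 3 replicates, of which 1 thresholded list is called conservative. Coordinates are on the dm6 build, per the labels. The aligner, the peak caller and their settings are not given in the sources used here. Which replicates were compared in each across-replicate list is not given either, so these lists are named by their number of peaks (3219, 3247 and 3534) beside the conservative list of 3515.

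Each region in the deposited lists has a signal, the authors' own measure of peak height, whose scale is not given in the sources used here. Signals were ranked, filtered, correlated and compared only within a list. The ranked lists hold the global irreproducible discovery rate (IDR) of each region, deposited as a −log10 value. The IDR is the expected share of irreproducible regions among those ranked at least as high in a pair of peak lists. From the values, every thresholded list held only regions with an IDR of at most 0.01, and lacked 60 to 100 ranked regions that also passed that rate. Per region the ranked lists also give a pair of deposited scores, the signals of the matching peak in the lists compared. Columns that held a constant or negative placeholder were not used.

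Peak coordinates were used with the Ensembl annotation BDGP6.54 (release 115) and the RefSeq sequence of the genome, whose repetitive bases are masked. The builds were compared first: on each of the 6 chromosome arms no peak ended past the reference length (0 ends on each arm). Peaks on other scaffolds (13 of the conservative list) were left out of every comparison by arm, gene or sequence, which left 3502 conservative peaks. Each summit was assigned to an intergenic region, intron, noncoding exon, 3′ UTR, coding exon or 5′ UTR and to the nearest transcription start site (TSS) of a protein-coding gene. A peak was called a promoter peak if its summit lay within 500 bp of such a TSS. In 81.3% of conservative peaks the summit lay at the midpoint of the peak, to within 1 bp, so summit positions there hold no information beyond the peak edges.

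Most comparisons set the conservative peaks against 57240 regions of the same ranked list that did not pass and lay over 1 kb from a passing peak. Promoter share and annotation were compared with Fisher's exact test, two-sided. A gene was called bound if a conservative summit lay within 500 bp of any of its TSSs, and 32 gene lists were tested by Fisher's exact test against all protein-coding genes with a ranked region at that distance. The tRNA, snRNA and snoRNA genes were tested against genes of every class. Presence of 33 motifs within 50 bp of the summit was compared with background regions matched on annotation and on GC content in bins of 5 percentage points, 3 per peak. The pool gave 8643 of the 10506 matched regions wanted, 1863 too few, so the match was incomplete: mean GC content was 33.5% in peaks and 35.5% in the matched regions. Every 6-mer was joined with its reverse complement, the 10 most enriched on arms 2L, 2R and X were chosen, and these were tested on arms 3L, 3R and 4 (Fisher's exact test, one-sided). P-values were adjusted by the Benjamini-Hochberg method over the 32 lists, the 33 motifs or the 10 words of 6 bases. Odds ratios have 95% Woolf intervals, with 0.5 added to each cell where a count was 0.

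Overlap of at least 1 bp made a peak shared. The shared fraction was compared with 1000 random placements of peaks on the same arms. The distribution over arms and the mean log2 signal at promoters were compared with permutation tests of 100000 resamples. Shares have exact (Clopper-Pearson) 95% binomial intervals, except that for a count of 0 the limit given is 3 counts of the total. Regions and genes are not independent replicates, so p-values and intervals computed over them cover counting error in these lists and not the spread between embryo collections. The number of sequenced reads per replicate was not used here, and the number of ranked regions is the only measure of depth taken from the files.

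The design, the gene lists and motifs, the rule for named items and a first set of alternatives were fixed before the data were examined. Further alternatives were added later and are named in the closing section. The rule took the 25 conservative peaks with the highest signal that overlapped a thresholded peak in all 3 replicates. It took the 4 bound members with the highest signal of each list past an adjusted p of 0.05, and up to 2 of each other list. It also took CG14050, every motif past the threshold and the 5 most enriched words of 6 bases on the test arms.

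The tests of gene lists, motifs, 6-mers, promoter share, arms and signal were checked on simulated lists of 3500 peaks drawn from regions that did not pass. The tests of annotation classes and those of the closing section were not simulated. In 20 lists with no effect, 2 of 640 gene list tests, 0 of 660 motif tests, 1 of 200 tests of 6-mers, 0 of 20 promoter tests, 2 of 20 arm tests and 0 of 20 signal tests fell under the threshold. The regions drawn from had a mean GC content of 45.8%, against 33.5% in the conservative peaks, and drawn regions also stayed in the background. These lists therefore did not meet the incomplete GC match, and cannot show how it affects the motif and 6-mer tests. Planted effects were recovered for the promoter share, the X, the signal, 3 of 3 motifs and 1 of 1 word. Of 3 gene lists favoured in the draw 2 were recovered. The list missed was that of cytosolic ribosomal proteins, of which only 22 of 75 members had a region that did not pass and could be drawn. With lists drawn from all ranked regions, 3 of 3 were recovered. Sharing between 3 lists that each kept 80 percent of 2000 peaks was recovered as well.

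Alternatives covered a stricter IDR of 0.002, each other across-replicate list, leaving out each replicate, the stronger peaks only, distances of 200 and 1000 bp from a TSS, other backgrounds, a window of 100 bp, other definitions of overlap and exchanged discovery and test arms. To leave out a replicate, the conservative peaks that overlapped a thresholded peak of both other replicates were used, because the files do not name the replicates of each across-replicate list. The summits and signals of these peaks still came from all 3 replicates, and the background was unchanged. For results from the conservative list, "without" a replicate therefore means a stricter filter on overlap and not peaks called without its reads. Some choices were made after values had been seen. The list of germline and piRNA genes had been tested against genes of every class by mistake and was then tested against protein-coding genes, as designed. The expected value of the simulated sharing test was also corrected. The tests of repeats and of ACAGTG at ribosomal promoters replaced first versions that could not have decided the question. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.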

Results

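The binding of the protein encoded by CG14050 was mapped by ChIP-seq in whole Drosophila embryos aged 0 to 24 hours, through an eGFP tag fused to the protein. The data were 3 biological replicates of 1 group, so every comparison was made between regions of the genome and none between conditions. The thresholded lists held 2155 peaks in replicate 1, 2433 in replicate 2 and 2282 in replicate 3 (mean 2290 ± 139 SD, n = 3). These came from 49504, 48710 and 46992 ranked regions, which is how deep each list reached; read depth was not used here. The conservative list, made by the authors across replicates, held 3515 peaks out of 63709 ranked regions, with a median width of 330 bp. All coordinates are on dm6, and gene positions are those of the Ensembl annotation. Signals are the authors' own peak heights and are compared only within a list.

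The tagged gene itself lies on X from 2324748 to 2326217 on the minus strand, inside the span of Raf, the gene of a kinase of the Ras pathway (X from 2295466 to 2343870). Each replicate, and each across-replicate list, had 3 peaks within 5 kb of CG14050. In the conservative list the strongest of these had its summit at 2325876, in the 5′ UTR of CG14050 and 92 bp from its TSS at 2325784, with a signal of 386 (rank 291 of 3515). A second peak had its summit at 2329486, in an intron, 2358 bp from the TSS of CG2854, with a signal of 315 (rank 442). The remaining peak lay in an exon of lncRNA:CR34052, with its summit at 2322127, 3657 bp from the CG14050 TSS, and a signal of 188 (rank 1075). The order of the 3 peaks was not constant, since the peak in the 5′ UTR was the strongest in replicates 1 and 3 (signals of 144 and 162) and the weakest in replicate 2 (signal of 58.1).

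**Figure D1:**
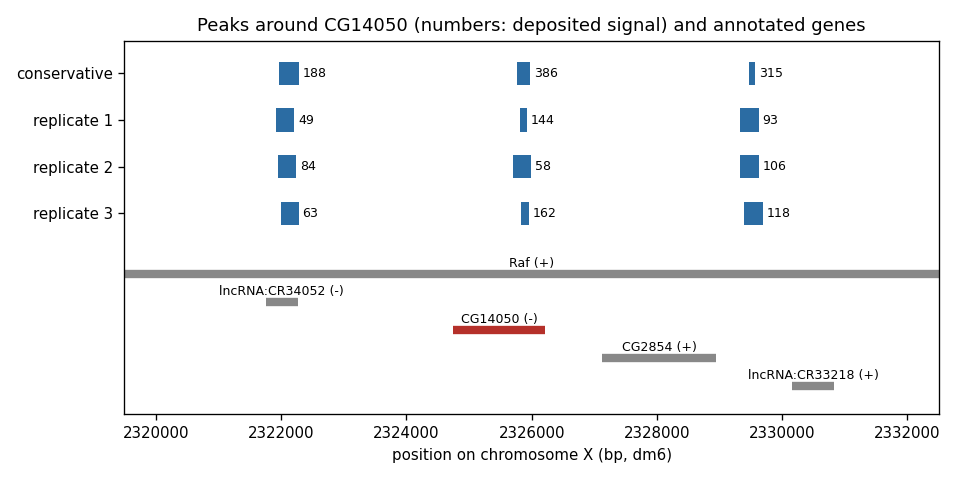
Peaks around CG14050 in the conservative list and in each replicate, drawn to scale against position on X (bp, dm6), with each peak's deposited signal beside it and the annotated genes underneath. All 4 lists have 3 peaks in the window, and the middle one (signal of 386 in the conservative list) lies at the 5′ end of CG14050.

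The replicates were compared to find how many peaks recurred. Peaks near the Ugalt, PNPase and mRpL41 promoters were among those found in each replicate, and 65.0% of the peaks of replicate 1, 57.4% of replicate 2 and 61.0% of replicate 3 overlapped a peak in both others (mean 61.1% ± 3.82 SD, n = 3). Peaks in no other replicate made up 16.7%, 21.3% and 16.2%. Randomly placed peaks gave a mean of 0.0087% (permutation test, one-sided, p = 0.001, the smallest that 1000 placements can give). Placement was uniform over each arm and was not limited to ranked regions. The test therefore shows only more overlap than uniform placement gives, and cannot tell specific binding from regions that any such precipitation would recover. Of the 3502 conservative peaks on the chromosome arms, 1422 overlapped a peak in each of the 3 replicate lists and had a median signal of 243. The 653 conservative peaks that overlapped none had a median signal of 83.1, with 106 and 135 for the 736 and 691 peaks found in 1 and 2 lists. Over all ranked regions, the pairs of signals behind the across-replicate lists had a mean Spearman correlation of 0.363 (SD 0.12, 4 lists), with 0.547 in the list of 3534 and 0.290 to 0.308 in the others. Within replicates the mean was 0.238 (SD 0.017, 3 lists). Over the peaks that passed, the mean of the across-replicate lists was 0.753. Which replicates, or parts of them, were paired in each list is not given in the sources used here, so these correlations are not a measure of agreement between replicates. They are across regions, which are not independent replicates, and no p-value was computed.

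**Figure D2:**
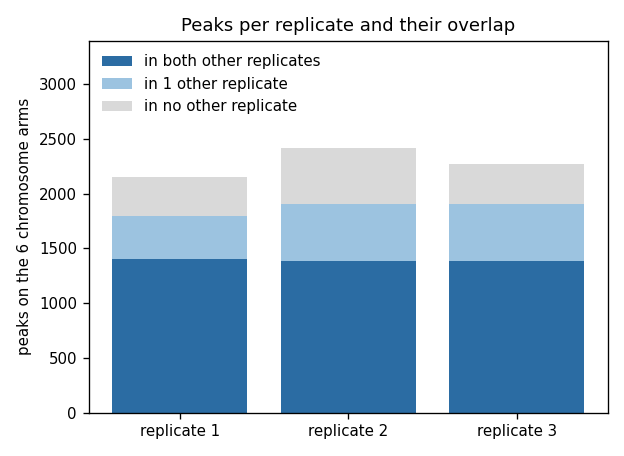
Number of peaks on the 6 chromosome arms in each replicate (vertical axis), with the bars divided by overlap of at least 1 bp with the other replicates. The part found in both others holds 1401, 1389 and 1387 peaks.

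The strongest peaks recurring in all 3 replicates lay mostly at promoters, and 25 of them were selected by signal. Of these, 17 had a summit within 500 bp of a protein-coding TSS and 8 lay farther away, 12 were intergenic, 8 intronic, 3 in a 5′ UTR and 2 in a noncoding exon. The highest signal, 2040, was that of a peak on 2L from 6612550 to 6612876 in an intron, 1018 bp from the TSS of CG11050. Next came a peak on X from 2703736 to 2704036 (signal of 2009), 45 bp from the TSS of Ugalt, which encodes a transporter of UDP-galactose, and peaks 88 bp from the TSS of CG14100 (3L, summit at 19590612, signal of 1981) and 11914 bp from that of CG13323 (2R, summit at 13035342, signal of 1892).

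Among the other named peaks, the summit at 31404662 on 3R lay in the 5′ UTR of PNPase, which encodes the mitochondrial polynucleotide phosphorylase (signal of 1781). The summit at 15217746 on 2R lay 129 bp from the TSS of mRpL41, a protein of the mitochondrial ribosome (signal of 1775). At eIF6, a factor of large ribosomal subunit maturation, the summit was at 23850401 on 2R in a noncoding exon (signal of 1386). Polyhomeotic (ph-p) and Psc, both of the Polycomb repressive complex that compacts chromatin, had peaks at 2137362 on X in an intron (signal of 1630) and at 12985210 on 2R, 4216 bp from the Psc TSS (signal of 1165). Chro, which encodes a chromatin protein of polytene interbands, had its summit at 22878900 on 3L in the 5′ UTR (signal of 1333), and a peak lay 567 bp from the TSS of HmgZ, which encodes an HMG-box protein (2R, summit at 21703397, signal of 1408).

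Most of the remaining named peaks lay 17 to 202 bp from a TSS. These included CenG1A, which encodes an Arf GTPase-activating protein (2L, summit at 13835475, signal of 1544), gish, which encodes a casein kinase I (3R, 16280720, signal of 1261), Fkbp14, a peptidyl-prolyl isomerase (2R, 21497315, signal of 1195), px (2R, 22514301, signal of 1322) and Art3 (3R, 15229525, signal of 1517). The remaining peaks near a TSS belonged to CG7601, CG18549, Tcs5, CG9147, CG5611 and CG8320, with signals from 1229 at CG8320 to 1566 at CG7601. Farther from a TSS were the peaks assigned to tara (3149 bp), CG32772 (1260 bp) and CG4004 (5086 bp).

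To find which parts of the genome were bound, summits were compared with ranked regions that did not pass. CG14050-eGFP peaks lay at promoters far more often than those regions did. Of 3502 conservative peaks, 1605 or 45.8% (44.2 to 47.5) had a summit within 500 bp of a protein-coding TSS, against 13.4% of the background (7697 of 57240 regions). The odds ratio was 5.45 (5.07 to 5.84) and Fisher's exact test, two-sided, gave p of at most 1e-300, the smallest value kept. The 3 replicate lists gave 48.3%, 47.0% and 48.8% (mean 48.0% ± 0.936 SD, n = 3). The median distance to a TSS was 664 bp in peaks and 3514.5 bp in the background, and 19.7% of peaks lay over 5 kb from a TSS. The size of the odds ratio depended on the list and its background. It was 2.99 in the list of 3534, where 21.3% of background regions lay at promoters, and 4.57 and 4.59 in the lists of 3219 and 3247. Its highest value was 6.61, without replicate 1. 

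Coding exons were almost free of summits, while 5′ UTRs and intergenic DNA held more of them than in the background. Only 38 peaks, 1.09% (0.769 to 1.49), lay in a coding exon, against 19.6% of background regions (odds ratio 0.045, adjusted p = 1.3e-254, Fisher's exact test). These background regions were not matched on GC content, whose mean within 50 bp of the summit was 45.8% in them and 33.5% in peaks. How far this difference accounts for the shares by annotation, or for the promoter share, was not tested. Intergenic summits made up 37.7% against 28.4% (odds ratio 1.53, 1.42 to 1.64) and 5′ UTRs 8.20% against 4.33% (1.97, 1.73 to 2.24). Introns held 48.9% against 42.8% (1.28, 1.19 to 1.37), but outside coding exons they held 49.4% of 3464 peaks against 53.2% of 46042 background regions (0.858, 0.801 to 0.919, adjusted p = 2.3e-05, Fisher's exact test). In that comparison intergenic DNA had an odds ratio of 1.13 (1.05 to 1.21) and 5′ UTRs 1.59 (1.40 to 1.80). The 3′ UTRs held 1.57% against 2.63% (0.59, 0.45 to 0.77). Noncoding exons did not pass the test (2.54% against 2.23%, adjusted p = 0.24 by the same exact test), except in the list of 3247 (odds ratio 1.27, adjusted p = 0.033). The odds ratio of coding exons was 0.021 to 0.0234 when a replicate was left out, and that of 5′ UTRs 1.17 in the list of 3534.

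**Figure D3:**
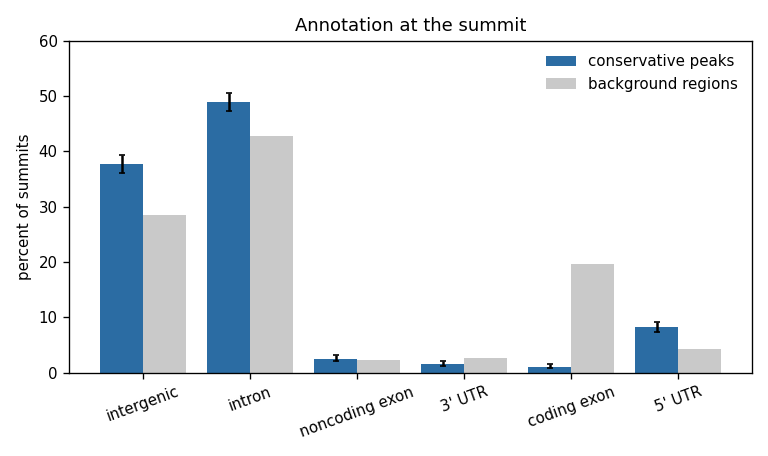
Percent of summits by annotation class (horizontal axis) in the 3502 conservative peaks and the 57240 background regions, with exact 95% binomial intervals on the peaks. Coding exons hold 1.09% of peaks and 19.6% of background regions.

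The genes at bound promoters were compared with 32 gene lists. Cytosolic ribosomal protein genes were bound most often, with 54 of 75 tested members (72% with an interval of 60.4 to 81.8) against 26.4% of other protein-coding genes. RpL7 had the strongest peak of the list (2L, summit at 10201039 in the 5′ UTR, signal of 494), before RpS27 (3R, 25247522, signal of 421), RpL23A (3L, 1668732, signal of 401) and RpL32 (3R, 30046254, signal of 366), each found in all 3 replicates. Genes of RNA polymerase II and the general transcription machinery were bound in 20 of 37 cases, or 54.1%. Among them were MED27, a subunit of the Mediator coactivator (3R, 5655012, signal of 357), Polr2B, a large subunit of the polymerase (3R, 14125690, signal of 355), Taf5, a subunit of TFIID (2R, 10879845, signal of 349), and Polr2H, a further polymerase subunit (3L, 21728753, signal of 264).

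The odds ratios were 7.17 (4.32 to 11.9, adjusted p = 1.1e-14) for the ribosomal genes and 3.23 (1.69 to 6.17, adjusted p = 0.0034) for the transcription machinery (Fisher's exact test). The first was 4.24 without replicate 1, 4.65 without replicate 3, 4.72 with the stricter IDR and 3.81 in the list of 3534. By the same exact test, the second call was lost in the list of 3534 peaks (odds ratio 1.47, adjusted p = 0.51), without replicate 2 (1.98, adjusted p = 0.48) and without replicate 3 (1.97, adjusted p = 0.49). In the tests, 1998 of 7439 protein-coding genes (26.9%) were bound.

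Chemosensory receptor, cuticle and tRNA genes were bound less often than other genes. None of 57 tested odorant, gustatory and ionotropic receptor genes was bound (0 of 57 allows a share of up to 5.26%), and none of 51 genes of epidermis and cuticle (up to 5.88%). Fisher's exact test gave odds ratios of 0.023 (0.0014 to 0.38, adjusted p = 4.1e-07) and 0.026 (0.0016 to 0.42, adjusted p = 2.0e-06). With a replicate left out these were 0.0455 to 0.0529 and 0.0508 to 0.0592, and in the list of 3534 they were 0.0659 and 0.0967. Genes of tRNAs were bound in 9 of 112 cases (8.04%) against 23.8% of other genes of every class (odds ratio 0.28, 0.14 to 0.55, adjusted p = 2.1e-04, Fisher's exact test), with an odds ratio of 0.126 without replicate 3 and 0.165 in the stronger peaks. Those with the strongest peaks were tRNA:Tyr-GTA-1-8 (3R, summit at 8669359, signal of 602), tRNA:Val-CAC-2-5 (3R, 19671866, signal of 204), tRNA:Phe-GAA-1-2 (X, 6744282, signal of 185) and tRNA:Gly-GCC-1-9 (2R, 18639319, signal of 132).

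Some lists did not pass after adjustment over the 32 lists, of which 10 had an unadjusted p under 0.05. Architectural and insulator protein genes were bound in 7 of 11 cases (adjusted p = 0.061, Fisher's exact test here and in the lists that follow), including Chro and Cp190, which encodes a cofactor of insulator proteins (signal of 376). This list passed in 7 of 12 alternatives, with adjusted p from 0.0032 to 0.48 over all of them. Cell cycle and replication genes were bound in 9 of 18 cases (exact test, adjusted p = 0.11), among them Dp, the partner of E2F (signal of 392), and RnrS, the small subunit of ribonucleotide reductase (signal of 231). Their odds ratio was 2.73, but 1.51 without replicate 1, 0.768 without replicate 2 and 0.762 without replicate 3. None of 13 dorsoventral patterning genes and none of 14 synaptic and neuronal genes was bound (allowing shares of up to 23.1% and 21.4%; exact test, adjusted p = 0.11 for both), and the synaptic list passed at 1000 bp from a TSS (adjusted p = 0.033). The snoRNA genes were bound in 9 of 71 cases (odds ratio 0.467, exact test, adjusted p = 0.11). They passed as bound less often in 4 of 12 alternatives, in the lists of 3219 (exact test, adjusted p = 0.005) and 3247 (0.002), at 200 bp (0.033) and against all annotated genes (4.8e-06), and had an odds ratio of 1.39 at 1000 bp and 0.775 without replicate 2.

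**Figure D4:**
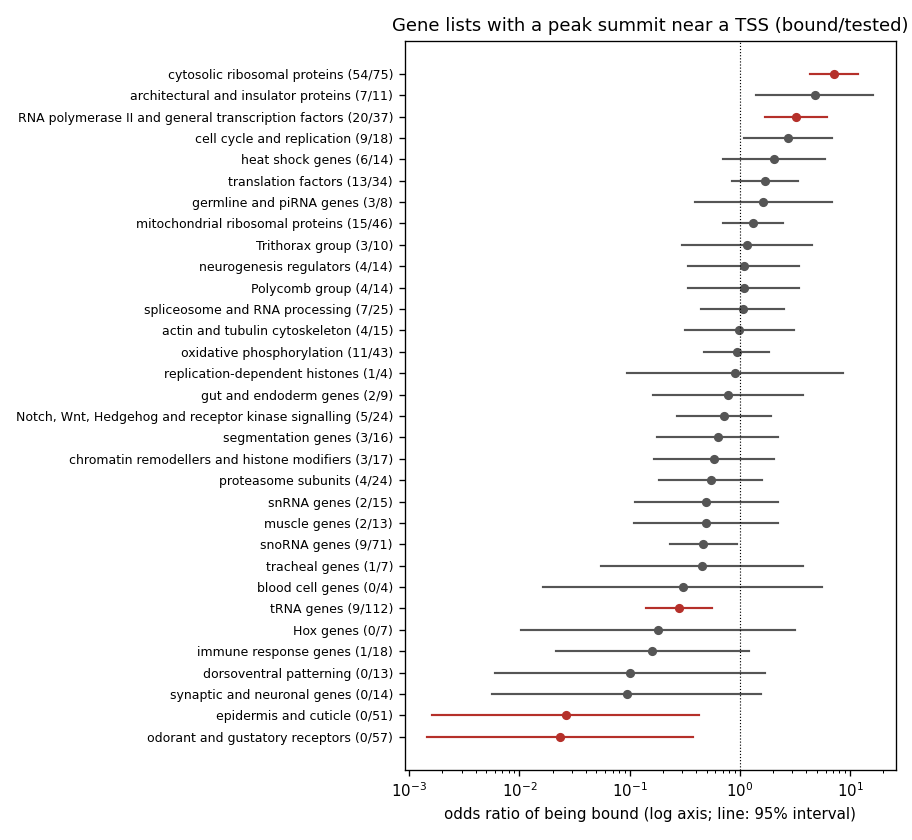
Odds ratio of being bound for each of the 32 gene lists (horizontal log axis, lines are 95% Woolf intervals), with bound and tested members in brackets and lists past the adjusted threshold in red. Cytosolic ribosomal proteins (54 of 75) are at the top and odorant and gustatory receptors (0 of 57) at the bottom.

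The sequence at the summits was compared with that of background regions matched on annotation and, incompletely, on GC content (33.5% in peaks, 35.5% in matched regions). The core of the CTCF site, AGRTGGCGC, the binding sequence of an insulator protein, was found within 50 bp of the summit in 1.17% of peaks and 0.231% of matched regions (odds ratio 5.11, 2.99 to 8.73, adjusted p = 1.8e-08 by Fisher's exact test over 33 motifs). The DRE, TATCGATA, bound by the promoter factor Dref, was found in 1.40% against 0.717% (1.96, 1.35 to 2.86, exact test, adjusted p = 0.0044). By the same exact test, the site of the muscle factor Mef2 had an odds ratio of 1.40 (1.21 to 1.63, adjusted p = 2.6e-04) and the TATA box 1.19 (1.09 to 1.31, adjusted p = 0.0024). Both sequences are AT-rich, and how much the remaining difference in GC content adds to their odds ratios was not tested. CA repeats (0.55, 0.38 to 0.79, adjusted p = 0.0051) and poly-A tracts (0.75, 0.65 to 0.86, adjusted p = 3.3e-04) were found less often in peaks by the exact test. In the exact test the DRE kept its call in 5 of 13 alternatives. The call was lost with the stricter IDR (exact test, adjusted p = 0.055), in the lists of 3219 (0.36) and 3534 (0.51) and in the stronger peaks (0.17). It was also lost without each replicate (0.11 to 0.81) and away from promoters, where the odds ratio was 0.897. The TATA box lost its call in 5 of 13, which were those without each replicate (exact test, adjusted p from 0.25 to 0.63), the stronger peaks (0.34) and peaks away from promoters (0.44). By the exact test Mef2 lost it without replicate 3 (odds ratio 1.28, adjusted p = 0.17) and away from promoters (0.37), as did CA repeats away from promoters (0.30). Poly-A tracts lost it in the list of 3534 (exact test, adjusted p = 0.86) and in promoter peaks alone (1), and had an odds ratio of 1.31 against flanks of the same peaks. The CTCF core lost its call in promoter peaks alone (odds ratio 2.38, exact test, adjusted p = 0.27) and had an odds ratio of 14.8 in the other peaks (adjusted p = 1.7e-11), a difference that was not itself tested. Its odds ratio was 9.32 without replicate 2, 8.49 with the stricter IDR, 3.04 in the list of 3534 and 3.00 with a window of 100 bp. CA repeats had odds ratios of 0.210, 0.307 and 0.232 without replicates 1, 2 and 3, 0.207 in the stronger peaks and 0.262 against flanks. Against flanks the DRE had 4.96, Mef2 2.73 and the TATA box 2.45. Flanks were not matched on GC content or annotation, so base composition may enter all values against them.

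Of the words of 6 bases chosen on arms 2L, 2R and X, 10 of 10 passed on the other arms. ACAGTG was the most enriched, within 50 bp of the summit in 7.73% of 1527 peaks against 4.35% of 3951 matched regions (odds ratio 1.84, 1.44 to 2.34, adjusted p = 4.6e-06, Fisher's exact test). It was followed by the AT-rich words AATAGT (1.49), ATATTA (1.42), TTAAAA (1.41) and TATTAA (1.35), whose adjusted p-values ran from 6.7e-07 to 1.4e-04. The matched regions on the test arms came from the same incomplete GC match (33.5% in peaks, 35.5% in matched regions). Passing there is thus no check on base composition, and how much of the enrichment of AT-rich words it explains was not tested. Against flanks of the same peaks ATATTA, TTAAAA and TATTAA had odds ratios of 3.79, 3.12 and 2.94. The flanks were not matched on GC content or annotation, so these higher values are no stronger evidence for the words. When words were chosen and tested again on smaller lists, 1 passed without replicate 1, 1 without replicate 2 and 0 without replicate 3. ACAGTG lost its call without replicate 1 (odds ratio 1.36, exact test, p = 0.058).

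The position of ACAGTG around the summit was profiled after its enrichment was seen. From 75 to 100 bp from the summit, copies whose 5′ to 3′ direction ran toward the summit numbered 78.8 per 1000 peaks and copies running away from it 19.4. In the background they numbered 12.2 and 10.9.

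**Figure D5:**
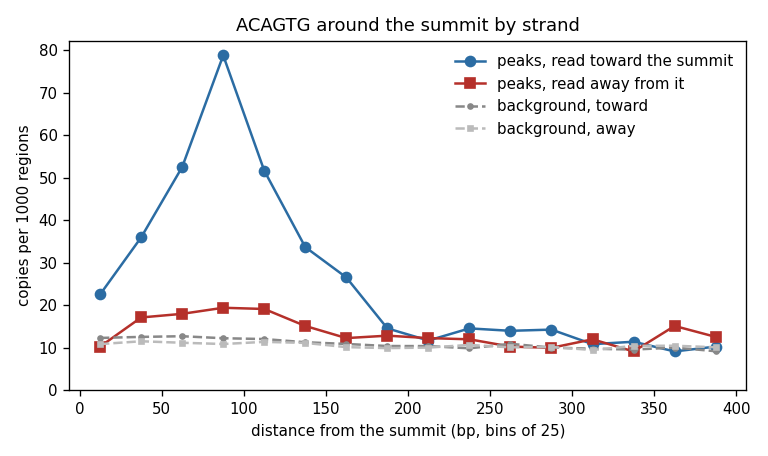
Copies of ACAGTG per 1000 regions (vertical axis) by distance from the summit in bins of 25 bp (horizontal axis), for 3502 conservative peaks and 57240 background regions and for each direction of reading. Copies read toward the summit in peaks reach 78.8 per 1000 at 75 to 100 bp, where copies read away reach 19.4.

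The X held more peaks and arm 3R fewer than the background regions. There were 691 peaks on X, 19.7% of the total against 14.7% of background regions, a ratio of 1.34 (1.25 to 1.43). Arm 3R had a ratio of 0.855 (0.802 to 0.910), and the intervals of arms 2L (0.970), 2R (0.986) and 3L (0.975) included 1. Chromosome 4 had 9 peaks and a ratio of 1.73 with a wide interval (0.792 to 3.28). The permutation test over the 6 arms gave p = 1e-05, the smallest that 100000 resamples can give. The size of the ratio on X depended on the reference. It was 1.17 when the expected shares came from protein-coding TSSs, and 1.65 in the list of 3534 with its own background.

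Promoter peaks were somewhat stronger than the others. Mean log2 signal was 7.20 (SD 1.33, 1605 peaks) at promoters and 6.95 (SD 1.29, 1897 peaks) elsewhere, a difference of 0.25 (permutation test, two-sided, p = 1e-05, the smallest possible). The difference was small beside the spread between peaks.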

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

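Peaks outside the chromosome arms used above were found in some lists and not in others, and none of them was tested further. Peaks on scaffolds that are not placed on an arm numbered 13 in the conservative list, 6 in the across-replicate list of 3534, 12 in replicate 2 and 7 in replicate 3. Replicate 1 and the lists of 3219 and 3247 had 0, although 121, 297 and 231 of their ranked regions lay off the arms. All of these peaks lay on unplaced scaffolds of the X, and none on the Y or on other scaffolds, where the conservative list's ranked regions numbered 50 and 234 against 236 on scaffolds of the X. The median signal of these conservative peaks was 77.6, below the median of 134 over the whole list.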

How the results depend on the processing

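Alternatives chosen after seeing the data were those with peaks of a signal of at least 30 and all but 2 of those for the 6-mers (other arms and flanks were planned), the tagged locus, the named peaks, the annotation classes, and the mean peak number without a replicate. Of 440 alternative values, 376 were labelled the same, 22 weaker, 13 stronger, 7 reversed and 22 moved. For tests, the same means an unchanged direction and side of the threshold. For counts it means a change within a fixed factor, and for means a change under 1 SD. Named peaks were selected for overlap with every replicate list and for signal, so they stayed without a replicate and in the stronger peaks by construction. The promoter share (32.1 to 55.9%, odds ratios of 2.99 to 6.61) and the ratio on X (1.17 to 1.65) kept their calls under every alternative run for them. So did the signal difference at promoters (0.18 to 0.34) and the shared fraction (50.6 to 73.0%). The calls of ribosomal, receptor, cuticle and tRNA genes held under every alternative as well. The stricter IDR left a mean of 1737 peaks per replicate, by construction, since fewer regions pass. The correlation of signals was 0.753 over passing regions, and the cause was not tested. That correlation has no value without a replicate, because the files do not name the pairs. Enriched gene lists numbered 1 in the list of 3534 and 5 at 1000 bp, and depleted lists 5 against all annotated genes. Enriched motifs numbered 1 to 2 without a replicate, 2 in the 1751 strongest peaks, 10 against flanks and 1 away from promoters, and depleted motifs 10 against flanks, 6 with a window of 100 bp and 1 away from promoters. Enriched 6-mers numbered 4 with the stricter IDR, 3 and 5 in the lists of 3219 and 3247, 0 to 1 without a replicate, 1 in the strongest peaks and 6 with a signal of at least 30. Leaving out a replicate or weaker peaks shortens the list by construction, and beyond that the cause was not tested. Conservative peaks kept without a replicate still had summits and signals derived from every replicate. Odds ratios reversed for cell cycle genes without replicate 2 (0.768) and 3 (0.762, against 1.51 without replicate 1), snoRNA genes at 1000 bp (1.39), the DRE away from promoters (0.897) and poly-A tracts against flanks (1.31), and the cause was not tested. Flanks, unlike the main background of the motifs, were not matched on GC content or annotation, which may enter the counts and odds ratios against them. Outside coding exons, which by construction removes their deficit from the shares, those of introns (0.858) and noncoding exons (0.923) reversed. No paired analysis was possible because there is 1 group. Read depth was not measured, and the number of members limits the smaller lists, such as the 4 tested blood cell and 7 Hox genes, where no bound member (0) allows shares of up to 75% and 42.9%.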

Other observations

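The tests of strand, of promoter direction and of facing copies and the test of other strongly expressed genes were chosen only after their results had been seen, and the interval in the test of extra copies was added after its value was known. The tests of repeats and of ACAGTG at ribosomal promoters were set after earlier tests of the same questions, before their own values were seen, except that the few peaks sharing a word were known.

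None of the following lists of developmental, signalling and immune genes passed the test, in either direction. Of the segmentation genes 3 of 16 were bound, among them cad and bcd, which encode maternal homeodomain proteins of the body axis (signals of 136 and 116). Of the neurogenesis regulators 4 of 14 were bound, including elav, which encodes a neuronal RNA-binding protein (X, summit at 523485, signal of 579). Bound members of the muscle list (2 of 13) were tin, which specifies the heart, and sls, which encodes the giant titin-like protein of the sarcomere (signals of 514 and 337). The gut list had 2 of 9 bound (fkh, signal of 194), the tracheal list 1 of 7 (trh, signal of 225), the germline and piRNA list 3 of 8 (bgcn and cuff), the Hox list 0 of 7 and the blood cell list 0 of 4. Signalling genes were bound in 5 of 24 cases, with sgg and spi the strongest, and immune response genes in 1 of 18 (imd, signal of 495). Adjusted p-values (Fisher's exact test) of these lists lay between 0.17 for the immune list and 1.

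Housekeeping lists other than those of cytosolic ribosomal proteins and the transcription machinery did not pass either at 500 bp, although translation factors and heat shock genes passed as bound more often at 1000 bp from a TSS, and histones as bound less often against all annotated genes. Translation factors had 13 of 34 bound (Fisher's exact test, adjusted p = 0.46), with eEF1gamma the strongest after eIF6 (signal of 446), mitochondrial ribosomal proteins 15 of 46 (adjusted p = 0.81), oxidative phosphorylation 11 of 43 (ND-ASHI, signal of 455), proteasome subunits 4 of 24 (Rpn3, signal of 225), splicing 7 of 25 (snRNP-U1-C, signal of 189), the cytoskeleton 4 of 15 (sqh, signal of 338), snRNA genes 2 of 15 and histones 1 of 4 (His2Av). Heat shock genes had 6 of 14 bound (exact test, adjusted p = 0.51), with Hsp27 and Hsp83, both chaperones, at signals of 649 and 386. Among chromatin lists, the Polycomb group had 4 of 14 bound (ph-p and E(z), the histone methyltransferase), the Trithorax group 3 of 10 (brm, the remodelling ATPase, signal of 802) and other remodellers 3 of 17 (Gcn5, a histone acetyltransferase, signal of 413).

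Some copies of the enriched word ACAGTG belonged to a longer sequence with a direction. ACAGTGG lay 25 to 150 bp from a conservative summit in 546 copies, of which 472 or 86.4% (83.3 to 89.2) were read toward the summit, against 54.2% in the background. The replicates gave 88.4%, 90.5% and 90.8%. The median distance of copies read toward the summit was 83 bp, but the window bounds this value, which was 85 bp in the background. A copy read toward the summit was found at 382 peaks (10.9%), against 2.12% of background regions. Of the 691 peaks on X, 17.1% had one. Of the 25 named peaks 3 had one, at CenG1A (2L from 13835543 to 13835551, minus strand, GTACAGTGG), CG5611 (3R from 27636057 to 27636065, plus strand, CAACAGTGG) and tara (3R from 16222581 to 16222589, minus strand, CCACAGTGG). Before the copies the commonest bases were G at 61.4% and C at 53.4%, against 38.5% and 37.7% in the background, and GCACAGTG was read toward the summit in 87.2% of 282 copies. This pattern was found by looking at the profiles of 10 words, of which 1 was followed up, and its window was read off the profile. From 150 to 400 bp the share was 56.3%. Of the other words, CAGGGGCG was read toward the summit in 86.2% of 65 copies, CTACGCCC in 12.2% of 41 and AAAAAAAA in 68.5%, while of CAGTG, contained in the longer word, 48.9% of 3155 copies were. That value mixed ACAGTG (74.1% of 1199) with copies of CAGTG not preceded by A, of which 33.6% of 1957 were read toward the summit (49.2% in the background).

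For this direction, a uniform shift of coordinates is excluded by the direction itself, since a shift puts both strands on the same side and the same copies, counted by strand, differed by 72.9 percentage points (67.1 to 78.6) in the share left of the summit. AT-rich DNA at the summit was no sufficient cause, since in the 946 peaks of highest GC content 72.3% (63.8 to 79.8) of copies were still read toward it, and repeats were not either, since 5.72% (3.8 to 8.2) of the copies read toward the summit lay in masked bases or in peaks sharing a word of 25 bases with another peak. In peaks over 500 bp from a protein-coding TSS the share was 86.9% (83.0 to 90.3), which argues against the direction of annotated protein-coding promoters as the whole cause and leaves other promoters open. Peaks with such a copy had a mean log2 signal 0.51 higher than the others (7.52 against 7.01, permutation p = 1e-05, the smallest possible), and 82 peaks had copies facing each other from both sides, against 15.3 expected from the shares on each side (exact binomial p = 5.3e-33). That expectation takes all peaks as equally likely to hold a copy. They were not, since 14.3% of peaks found in 3 replicate lists had one, against 5.97% of those found in none. The excess therefore cannot by itself show that copies come in pairs. No control library was analysed here, so a property of open chromatin or of any such precipitation stays open, and no biological explanation of the direction was tested.

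For the frequent binding of cytosolic ribosomal protein promoters, GC content was not a sufficient explanation, since the odds ratio within strata of promoter GC content was 6.21 (3.76 to 10.3). Mere presence of ACAGTG within 500 bp of the TSS was not either, because the odds ratio within genes with and without the word was 7.22 (4.33 to 12.1). The word was about as common at tested ribosomal genes (49.3%) as at others (46.7%, odds ratio 1.11, 0.705 to 1.75), so dividing genes by it could change little. Whether ACAGTGG read toward the summit has a part at these promoters was not tested. Of the 38 tested ribosomal genes without ACAGTG within 500 bp of a TSS, 26 were bound (68.4%), against 21.8% of 3924 other genes without it. Strong expression stays open, since expression was not measured here and the lists pooled to test it (oxidative phosphorylation, translation factors, proteasome and cytoskeleton, 32 of 116 bound, odds ratio 1.04, 0.689 to 1.56) were picked after their values had been seen, and translation factors passed at 1000 bp. Preferential recovery of these promoters in any precipitation from embryos stays open too, and no biological explanation was tested.

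For the 3 peaks around CG14050, a dense stretch of peaks may be sufficient, since 7.74% of 2196 protein-coding genes of the X had as many within 5 kb, although the median was 0. Extra copies of the region in the tagged line could also raise signal there. The median signal of 25 regions that did not pass within 20 kb lay at percentile 81.7 among genes of the X, under the bound of 95 set beforehand, but a bootstrap interval of 34.5 to 96.2, added after the value was seen, reached past it. This explanation therefore cannot be told apart from an ordinary stretch of the X with so few regions.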
